A study of Gallus gallus with 24 samples.

How the data were processed

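Genomic DNA of erythrocytes from 24 birds was hybridized in pairs to 12 arrays on 3 slides, with 4 arrays per slide. The group, dye and array of each bird were taken from the labels, per which each group held 8 individuals. Per the labels' protocols the DNA was isolated by proteinase digestion and phenol and chloroform, and was labelled enzymatically by Agilent's protocol for copy number arrays. Per the file headers the scans were read with Agilent Feature Extraction 10.7.1.1 (protocol CGH_107_Sep09), and probe positions refer to the galGal3 build.

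The deposited processed signal of each channel is an intensity on a linear scale. Per the file headers it was background-subtracted, detrended over the slide and scaled with 1 linear dye factor per channel, with no lowess term. The deposited median spot signal and local background are raw intensity values. The deposited LogRatio column is log10 of red over green, and it equalled log10 of the ratio of the processed signals within 0.0001 for 99.984% of spots. The deposited flags for saturation, outliers and spots well above background are marks of 0 or 1, per the file headers. No further processing by the authors was given in the sources used here.

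From these, log2 of red over green processed signal was computed for the 42495 non-control spots of an array and centred on the array's median over all of them, with no loess or quantile step, since a copy number array can hold many probes that shift one way. Spots flagged as outliers, 1 to 128 per array, were left out, and spots of the same probe were averaged. In all, 15297 probes had 2 spots, and all of these were numbered. After centring, the median log2 ratio of chromosomes 1 to 3 lay between -0.15 and -0.03, so centring on those chromosomes moves an array by up to 0.15. Saturated spots were kept. They made up 6.91% to 10.3% of red and 0.0165% to 3.97% of green spots, and on slide 3 the green saturation flag was never set although 1.838% of green spots lay at the ceiling. In at least 1 channel, 10 GGA16 probes and 2965 numbered probes were saturated. Between 99.8% and 99.9% of spots were well above background in both channels. The highest absolute correlation of log ratios between 2 arrays was 0.86, so no array was a copy of another.

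Each probe was fitted with limma 3.58.1 in R 4.3.3. The dose model had an intercept for the dye and a slope on the log2 ratio of labelled copies (red over green). A second model had coefficients for 3X and 4X against 2X, from which the pairwise contrasts were taken, and the departure was (3X - 2X) minus 0.58 times (4X - 2X). Moderated statistics were adjusted by Benjamini-Hochberg over the 27198 probes with a threshold of 0.05, two-sided. All 12 arrays entered each fit, so the 3 kinds of pair shared one spread. The mean of the GGA16 probes per array was tested by permuting the doses over the arrays 100000 times, or over all orders with 8 arrays or fewer. Bird levels were the median log2 processed signal of a chromosome's probes in the bird's own channel, relative to chromosomes 1 to 3 and to the mean of the 12 birds of that dye. Groups of birds were compared by two-sided exact permutation tests adjusted over the 3 comparisons. The 2 birds of an array share its spots, so their levels are not fully independent.

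The fits were tested on simulated data with each probe's own residual spread and 200 changed probes among 27198. In the dose model 92% of slopes of 1 and 84% of slopes of 0.5 were recovered, with 14 false calls. At a slope of 1 the contrasts recovered 84% (3X against 2X), 90% (4X against 2X) and 78% (4X against 3X). At a slope of 0.5 they recovered 60%, 84% and 42%. The simulated noise was independent between probes, which leaves out variation that all probes of a chromosome share on an array. The changed probes were drawn from all probes, whose dose slopes had a median standard error of 0.0505, against 0.147 for GGA16 probes. The recovery rates therefore do not apply to GGA16 probes.

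The test of unplaced regions, planned with at least 2 probes of a named contig, was replaced by numbered probes taken one at a time, because the files pair their numbers with no contig. The gene lists fixed before the data were examined were not tested, because the files name no genes, and GC correction was not run, because probe sequences were not used here. The rule for named items, also fixed before the data were examined, was applied to probes: up to 10 numbered probes with the largest positive slopes past the threshold and positive in the mean of all 3 kinds of pair, up to 5 with the most negative slopes, and up to 3 per direction for each contrast. This adaptation was made after the probe names were seen. The call on chromosome 2, numbered probes called but outside the rule and the stretches of GGA16 were chosen after their values were seen.

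The alternatives listed before the data were examined were normexp on the median signals with an offset of 50 (the mean signals were not used here), the LogRatio column, other centring, loess, a filter on spots well above background on at least 9 arrays, keeping outliers, no dye term, the slide as a block and each slide alone, a replicate block, leaving out each array, trend with robust moderation, array weights, a minimum slope of 0.5, direct arrays only, and the median of GGA16 probes. Those added after the data were seen were the chromosome Z ratio as a covariate, with and without the array of the bird labelled tetrasomic 2, the measured GGA16 ratio in place of the label together with the chromosome Z covariate, leaving out saturated probes, and the level of single birds.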

Results

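Genomic DNA from the red blood cells of 24 chickens was compared by array comparative genomic hybridization, in which DNA of 2 birds carrying different fluorescent dyes competes for the same 12 custom oligonucleotide arrays. The birds were labelled as carrying 2, 3 or 4 copies of microchromosome 16 (GGA16), the small chicken chromosome that holds the major histocompatibility complex and the nucleolus organizer, with 8 birds labelled disomic (2X), 8 trisomic (3X) and 8 tetrasomic (4X). Each bird was on 1 array, and each of the 3 kinds of pair (3X with 2X, 4X with 2X, 4X with 3X) was on 4 arrays, with 2 arrays in each dye orientation. An array measured 27198 probes. Of these, 2546 had a position in the galGal3 assembly: 500 each on chromosomes 1, 2, 3, 16 and Z, and 46 on W. The other 24652 carried only a number, with no contig, position or gene in the files, and are called numbered probes here. The median spot signal of an array lay between 874 and 1971 in the green (Cy3) channel and between 2373.5 and 3384.5 in the red (Cy5) channel, over local backgrounds of 29.5 to 34 and 133 to 156. Precision was limited by the number of arrays.

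The first comparison asked whether the DNA dose of GGA16 followed the labelled copy number. DNA of GGA16 was more abundant in birds labelled with more copies on 11 of the 12 arrays. Averaged over the 500 placed GGA16 probes, 4X birds exceeded 2X birds by 0.88 ± 0.11 on the log2 scale (SD, n = 4 arrays), a ratio of 1.83, where the labelled dose gives a log2 ratio of 1. The 3X birds exceeded 2X birds by 0.40 ± 0.27 (SD, n = 4), against a labelled log2 ratio of 0.58. The 4X birds exceeded 3X birds by 0.12 ± 0.66 (SD, n = 4), against a labelled 0.42, and this difference was smaller than the spread between arrays. On 1 of these arrays the bird labelled tetrasomic 2 had less GGA16 DNA than trisomic bird 2, at a log2 ratio of -0.74. Without that array the 4X to 3X ratio was 0.40 ± 0.41 (SD, n = 3). More of these 3 arrays carried the 4X bird in Cy5 than in Cy3, so this mean is not balanced for dye. Over all 12 arrays the GGA16 probes had a median dye offset of 0.18 (log2, red minus green).

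**Figure D1:**
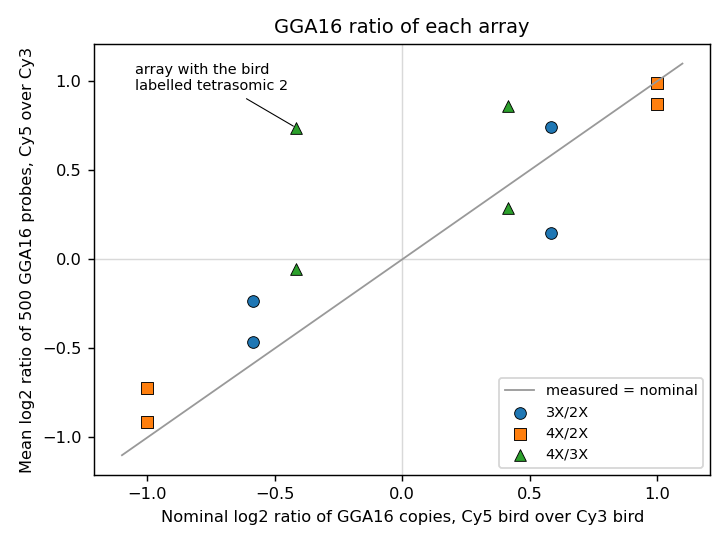
Mean log2 ratio of the 500 placed GGA16 probes on each of the 12 arrays (vertical axis, Cy5 over Cy3) against the log2 ratio of labelled copies (horizontal axis); symbols mark the kind of pair and the line marks equality. The array with the bird labelled tetrasomic 2 lies on the wrong side of 0, at 0.74 where the label gives -0.42.

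Regressed on the labelled log2 dose, the GGA16 mean rose with a slope of 0.764 ± 0.150 (SE, n = 12 arrays; two-sided permutation test, p = 0.001), where 1 is the labelled dose. Within the slides, each with 4 arrays, the slopes were 0.737, 0.791 and 0.750, with exact permutation p of 0.25, 0.0833 and 0.0833, and 0.0833 is the smallest p that 4 arrays allow. Leaving out the array with the bird labelled tetrasomic 2, chosen for its ratio, gave a slope of 0.831 ± 0.0989 (SE, n = 11 arrays).

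Levels of single birds, taken from their own channel relative to chromosomes 1 to 3, showed the same order. The GGA16 level was -0.42 ± 0.10 in disomic, 0.09 ± 0.23 in trisomic and 0.35 ± 0.34 in tetrasomic birds (log2 units, SD, n = 8 each). Trisomic exceeded disomic birds by 0.51 and tetrasomic exceeded disomic birds by 0.76 (two-sided exact permutation tests over birds, adjusted p = 0.0014 for both). The tetrasomic and trisomic groups differed by 0.25, which did not pass the test (adjusted p = 0.105, exact permutation). The bird labelled tetrasomic 2 had a level of -0.47, inside the range of the disomic birds (-0.59 to -0.28), whereas the other 7 tetrasomic birds had levels of 0.34 to 0.58. Without it the tetrasomic birds exceeded the trisomic birds by 0.37, a value given without a test because the bird was left out for its level. Trisomic birds 1 and 7, at -0.19 and -0.31, were the lowest of their group, and bird 7 also lay inside the range of the disomic birds.

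**Figure D2:**
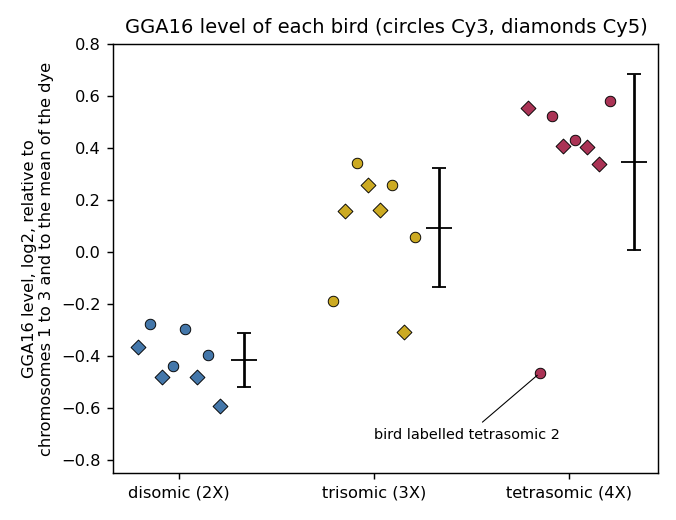
GGA16 level of each of the 24 birds (vertical axis, log2 units relative to chromosomes 1 to 3 and to the mean of the birds with the same dye) by labelled group, with circles for Cy3, diamonds for Cy5 and bars for the mean ± SD of 8 birds. The bird labelled tetrasomic 2 lies at -0.47, among the disomic birds.

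The next comparison asked which probes followed the GGA16 dose. In limma's dose model 338 probes rose with the labelled dose and 2 moved against it at an adjusted p under 0.05. Of the 338, 321 were among the 500 placed GGA16 probes (64.2%), 16 were numbered probes and 1 was on chromosome 2. The slopes of the placed GGA16 probes had a median of 0.862 (interquartile range 0.653 to 0.923), and 495 of the 500 were positive. By contrast, median slopes on chromosomes 1, 2 and 3 were -0.0174, -0.0155 and -0.0157, and the 1 call among them lay on chromosome 2 at 374779 to 374838 (galGal3), with a slope of 0.281 ± 0.0562 (SE, n = 12 arrays; limma adjusted p = 0.0284). The count rested on particular arrays: it fell to 0 without the array of tetrasomic bird 3 and disomic bird 3, fell to 0 without the array of tetrasomic bird 8 and disomic bird 8, and was 179 without the array of disomic bird 4 and tetrasomic bird 4. Without the array of the bird labelled tetrasomic 2 it was 420. With the chromosome Z ratio as a covariate over all arrays the count was 0. With array weights it was 743, with 525 probes against the dose.

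Along the assembled part of GGA16 in galGal3, the dose response was not even. Between positions 70001 and 200000 the 194 probes had a median slope of 0.876 (interquartile range 0.807 to 0.917) and 177 of them followed the dose. Between 20001 and 70000 the 68 probes had a median slope of 0.591 (0.355 to 0.844), 27 had slopes under 0.5 and 22 followed the dose. A further low stretch lay between 200001 and 220000, where 13 of 33 probes had slopes under 0.5. Between 250001 and 370000 the median slope was 0.924, the highest of the 7 stretches, but the median standard error was 0.224, against 0.139 between 70001 and 200000, and 13 of 90 probes followed the dose. Without the array of the bird labelled tetrasomic 2, 51 of these 90 probes followed the dose, and 39 of the 68 between 20001 and 70000. In all, 79 of the 500 GGA16 probes had slopes under 0.5. The stretches were set after the slopes were seen, and a gene annotation of this assembly was not used here.

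**Figure D3:**
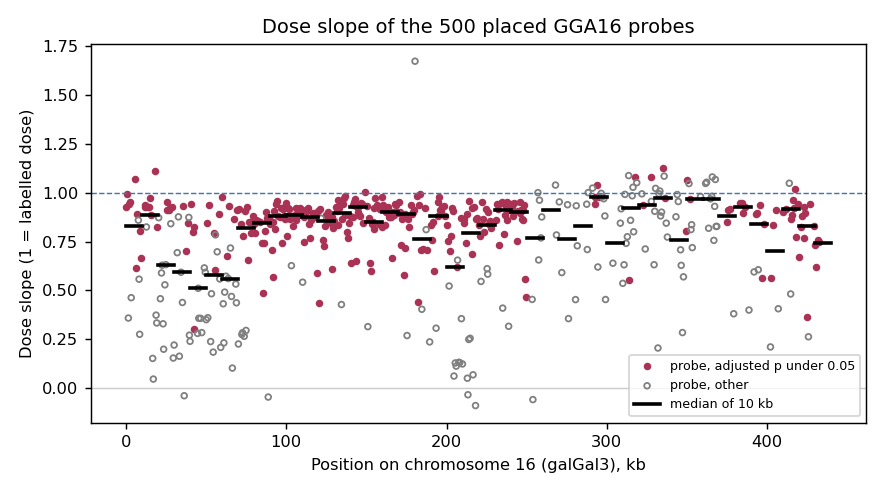
Dose slope of each of the 500 placed GGA16 probes (vertical axis, 1 is the labelled dose) against its start on chromosome 16 of galGal3 (horizontal axis, kb); filled points passed adjusted p 0.05, open points did not, and bars are medians of 10 kb windows. Slopes lie near 0.876 between 70001 and 200000 and are lower and more scattered between 20001 and 70000 and between 200001 and 220000.

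The title of the study names the assignment of unplaced sequence to GGA16. The numbered probes may hold such sequence, but they had no contig or position to show it. Among 24652 numbered probes, 16 followed the dose and 2 moved against it. The 10 with the largest slopes, all positive in the mean of each kind of pair, were probes 9759, 11388, 11389, 13552, 19401, 19402, 28051, 28052, 28053 and 28054, with slopes between 0.532 and 0.936. Probe 28052 had the largest slope, 0.936 ± 0.143 (SE, n = 12 arrays; limma adjusted p = 0.00852). Its log2 ratios were 1.00 ± 0.19 for 4X over 2X and 0.54 ± 0.29 for 3X over 2X (SD, n = 4 each), both larger than the spread between arrays. The 4X to 3X ratio was 0.24 ± 0.87 (SD, n = 4), smaller than the spread, with the array of the bird labelled tetrasomic 2 included. Its neighbour in number, probe 28051, had a slope of 0.920 ± 0.143 (limma adjusted p = 0.00852) and ratios of 1.01 ± 0.20 for 4X over 2X and 0.52 ± 0.17 for 3X over 2X (SD, n = 4 each).

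Probes 19401 and 19402 had slopes of 0.862 ± 0.122 and 0.713 ± 0.104 (SE, n = 12 arrays), and probes 11388 and 11389 had slopes of 0.625 ± 0.0998 and 0.532 ± 0.0970. Probes 28053 and 28054 had slopes of 0.656 ± 0.139 and 0.705 ± 0.0946. Probes 9759 and 13552, with no called neighbour in number, had slopes of 0.748 ± 0.0936 and 0.715 ± 0.138. None of these 10 probes had a saturated spot on any array. The other 6 called numbered probes had slopes between 0.191 and 0.420. The 2 that moved against the dose, probes 2660 and 16603, had small slopes of -0.151 ± 0.0300 and -0.103 ± 0.0217 (limma adjusted p = 0.0277 and 0.0406). The 10 largest slopes kept their sign in all 30 alternative settings, but each lost its call in some of them: probe 28053 in 17, probe 13552 in 12 and the other 8 probes in 7 or 8. Probes 2660 and 16603 lost theirs in 15 and 24. The count of 16 fell to 0 without the same 2 arrays as the main count, was 9 without the array of disomic bird 4 and tetrasomic bird 4, and rose to 111 without the array of disomic bird 5 and trisomic bird 7.

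**Figure D4:**
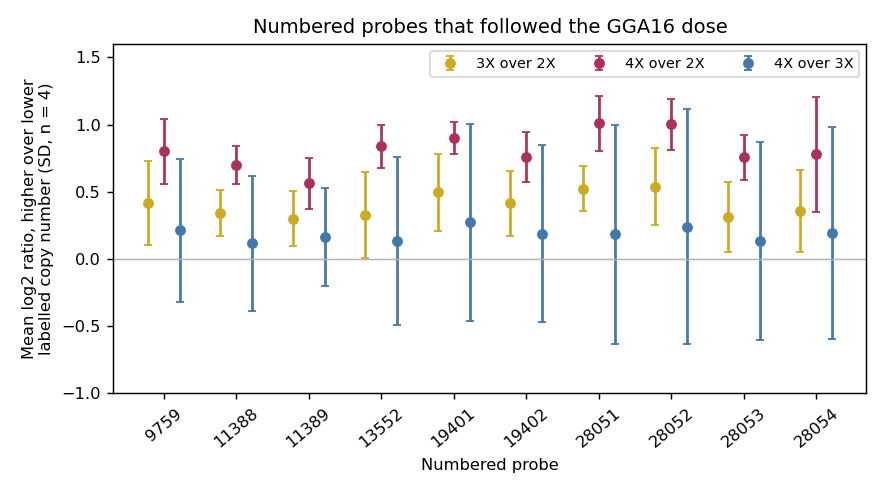
Mean log2 ratio of the higher over the lower labelled copy number (vertical axis; bars are SD over 4 arrays) for the 10 numbered probes with the largest called dose slopes (horizontal axis), by kind of pair. For probe 28052 the mean is 1.00 for 4X over 2X and 0.54 for 3X over 2X, and the 4X over 3X means include the array of the bird labelled tetrasomic 2.

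The 3 groups were then compared in pairs, with the 12 arrays in one limma model. Between 4X and 2X birds 311 probes were higher and 2 lower in 4X birds, and 295 of the higher ones lay on GGA16, 15 were numbered and 1 was on chromosome 2. Among the 311, the largest differences lay on GGA16 (galGal3) at 18048 to 18096, with 1.11 ± 0.149, at 335306 to 335358, with 1.11 ± 0.214, and at 5658 to 5707, with 1.08 ± 0.197 (log2, SE; limma adjusted p = 0.0181, 0.0329 and 0.0251). The 2 lower probes were at 1563091 to 1563150 on chromosome 2, at -0.92 ± 0.184, and numbered probe 19649, at -0.16 ± 0.0313 (limma adjusted p = 0.0384 and 0.0374). The count of 311 fell to 0 without any 1 of the 4 arrays that compared 4X with 2X birds directly. Without each of the other 8 arrays it lay between 154 and 640, the latter without the array of disomic bird 5 and trisomic bird 7. With the chromosome Z ratio as a covariate the count was 0, with array weights 524, and with the direct arrays only 1228.

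Between 3X and 2X birds limma called 0 probes in either direction, with 650 at an unadjusted p under 0.05, 416 of them on GGA16. The median difference of the GGA16 probes was 0.58. The arrays that compared 3X with 2X birds directly gave a mean of 0.40. Without the array of the bird labelled tetrasomic 2, 161 probes were higher in 3X birds. Between 4X and 3X birds limma also called 0 probes, with 1370 at an unadjusted p under 0.05, and the GGA16 median difference was 0.24. The arrays that compared 4X with 3X birds directly gave a mean of 0.12. For departures of 3 copies from the line through 2 and 4 copies, limma called 0 probes, with 717 at an unadjusted p under 0.05, of which 1 lay on GGA16. Chance alone gives a share of about 0.05 of the 27198 probes, which 1370 is near and 650 and 717 are below. By contrast, 416 of the 500 GGA16 probes passed between 3X and 2X birds, and 99 between 4X and 3X birds.

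Sex chromosome levels split the birds into 2 sets, and the groups held unequal numbers of each, a difference that did not pass its test. In chickens the hen is the ZW sex and the cock ZZ. All 9 birds with a chromosome W level above 0 had a Z level below 0, and all 15 other birds had a Z level above 0. The 9 were 1 of 8 disomic, 3 of 8 trisomic and 5 of 8 tetrasomic birds (two-sided Fisher's exact test over the 3 groups, p = 0.171). On every array that compared 4X with 2X birds directly, the 4X bird was one of the 9 and the 2X bird was not. The 1 disomic bird of the 9 was disomic bird 5. Without its array, numbered calls were 111 and calls for 4X over 2X were 640, and every disomic bird left was in the other set. The dose slope of the Z probes had a median of -0.577 and that of the W probes was positive for all 46, but limma's dose model called 0 of either at adjusted p under 0.05, with 355 of 500 Z probes negative at an unadjusted p under 0.05. W probes in birds without a W signal lay near background, so no fold is given for them.

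With the chromosome Z ratio of each array added to the dose model, an alternative chosen after the data were seen, the GGA16 slope was 0.620 ± 0.172 (SE, n = 12 arrays; permutation p = 0.00871), but limma called 0 probes for the dose, with the slope of probe 28052 at 0.824 ± 0.168 (SE; adjusted p = 0.118). For this probe the slope was smaller and its standard error larger with the covariate. With the same covariate and without the array of the bird labelled tetrasomic 2, left out for its ratio, 348 probes rose with the dose, of which 336 lay on GGA16 and 12 were numbered. Of the 16 numbered probes called before, 11 were among these 12, and all 10 probes with the largest slopes were included.

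**Figure D5:**
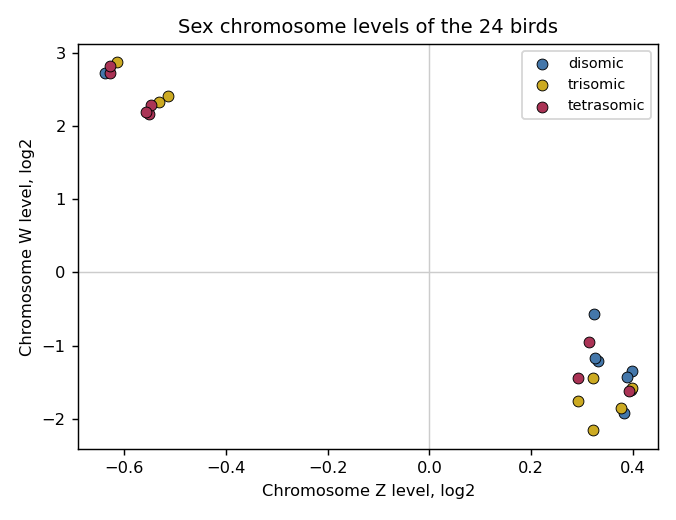
Chromosome W level (vertical axis) against chromosome Z level (horizontal axis) of the 24 birds, each in log2 units relative to chromosomes 1 to 3 and to the mean of the birds with the same dye, coloured by labelled group. The birds form a set of 9 with high W and low Z levels, 5 of them tetrasomic, and a set of 15 with the reverse.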

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

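Values per bird and per array were screened for a value far from the rest of its group, and 4 of 48 groups held one, where chance gives about 1 in 20. The tests of the bird labelled tetrasomic 2, of the numbered probes with the chromosome Z covariate and of neighbouring GGA16 probes were chosen after those results were seen.

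The bird labelled tetrasomic 2 had a GGA16 level of -0.47, far below the other 7 tetrasomic birds, the nearest of which was at 0.34. An exchange of labels between the 2 birds of its array is argued against by the level of trisomic bird 2, 0.16, below the lowest tetrasomic bird of the same dye (0.34). Noise of the array stays open: its SD over probes of chromosomes 1 to 3 was 0.206, above the median of the 12 arrays (0.184) and below the highest (0.247), and the spread of single probes does not measure an error shared by a chromosome. A wrong label for a bird without extra copies stays open too: -0.47 lies within the range of all 8 disomic birds, but just below the 4 disomic birds of the same dye (-0.44 to -0.28). No biological explanation was tested.

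Disomic bird 5 had a chromosome Z level of -0.64, where the other disomic birds began at 0.32, and was the only disomic bird with a W level above 0 (2.72, a value that depends on background, since W probes of birds without a W signal lay near it). Its values lie with those of the 8 birds of the other groups that had high W and low Z levels. Across arrays the Z median fell with the GGA16 dose with a slope of -0.576, which became -0.0803 once the W ratio was in the model. The W and Z levels set apart the same birds, so the W ratio stands in for the Z ratio and this drop cannot test an explanation by sex. The groups did hold unequal numbers of birds with high W and low Z levels. The sex of the birds was not given in the sources used here. With the Z covariate over all 12 arrays none of the 16 numbered probes called for the dose kept its call: their median slope went from 0.641 to 0.527 and the median standard error from 0.0958 to 0.113. All 16 stayed above 0 by more than 2 standard errors in that fit, the lowest by 3.31. This cannot decide whether sex alone gives these slopes, since the 16 were chosen for their slopes on the same arrays. A part played by sex stays open.

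Probe 28051 had a log2 ratio of 0.77 on the array of disomic bird 2 and trisomic bird 4, where the other 3 arrays of 3X and 2X birds were at 0.45 or below.

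Some placed GGA16 probes followed the dose weakly, 79 of 500 with slopes under 0.5. Saturation is argued against as the cause for most of them, since 91.1% had no saturated spot on any array. For the rest it stays open. Only 10 of the 500 GGA16 probes had a saturated spot, and most of these 10 were among the 79. Neighbouring probes had slopes somewhat more alike than in shuffled orders. Their mean absolute difference was 0.216, against a mean of 0.255 and a lowest of 0.227 in 10000 shuffled orders. Sequence shared with other parts of the genome could lower slopes and raise signals; the Spearman correlation of slope with mean signal across GGA16 probes, which are not independent, was -0.0861 and left this open. The 2 sets differed in median log2 signal, 11.34 for slopes under 0.5 and 10.06 for the others. Across stretches the order was mixed. In the low stretches the median signal was 10.31 (20001 to 70000) and 8.33 (200001 to 220000), against 9.77 between 70001 and 200000. It was 11.70 between 250001 and 370000, where the median slope was highest.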

How the results depend on the processing

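The GGA16 dose slope was positive in all 30 alternatives (0.620 to 0.831), and passed its test in 27. Trend with robust moderation does not enter this regression, so it could not move the slope. Leaving out the dye term or blocking by slide kept the slope at 0.764 by the balance of the design. The slope did not pass within slide 1, 2 or 3 alone (0.737, 0.791 and 0.750), where 4 arrays cannot give an exact permutation p under 0.05. Under the other alternatives the main dose count stayed within 1.5 times of 338 with other signals, centring, loess, filters, no dye term or the slide as a block. It was 743 with array weights, with 525 probes against the dose, 11 on other placed chromosomes and 289 numbered, and 524 probes higher in 4X than 2X. With the chromosome Z covariate over all arrays the counts for the dose, numbered probes, probes against the dose, other chromosomes and 4X over 2X were all 0. With that covariate and without slide 1 array 2 (the bird labelled tetrasomic 2), 1 probe moved against the dose, 0 lay on other chromosomes, 116 were higher in 3X than 2X and 2 departed from the log2 dose. Each slide alone gave 0 for all 4 dose counts. Slide 1 gave 0 for 4X over 2X. Slide 2 gave 485 (3X over 2X), 525 (4X over 2X), 215 (4X over 3X) and 496 departures. Slide 3 gave 30 (4X over 3X) and 276 departures. Slide 1 held no array of 4X with 2X birds, slide 2 none of 3X with 2X and slide 3 none of 4X with 3X. Those contrasts were therefore indirect within the slide. Each contrast fit of a slide put 3 coefficients on 4 arrays, so little was left to estimate the spread. The direct arrays only gave 1228 for 4X over 2X and 157 for 4X over 3X, and on the first of these the birds also differed in W level.

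Probes against the dose, 2 at first, were 1 with centring on chromosomes 1 to 3, loess or the slide as a block and 0 without a dye term. The call on another chromosome was lost (0) with normexp, centring on chromosomes 1 to 3 and loess. Numbered calls were 8 without a dye term, 10 with a slope of at least 0.5 and 25 with 2 choices changed together, the measured GGA16 ratio for the label and the chromosome Z covariate. Leaving out each array gave ranges of 0 to 486 for the dose, 0 to 111 for numbered probes, 0 to 11 against the dose, 0 to 1 on other chromosomes, 0 to 161 for 3X over 2X and 0 to 640 for 4X over 2X, and the slope ranged from 0.689 to 0.831. The count was 0 without slide 2 array 1 or slide 3 array 4. The causes were not tested.

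Replicate numbers gave no sign of pairing birds across arrays. Deviations of birds with the same number in different groups, on different arrays, correlated between -0.58 and 0.52 over 16 pairs (median -0.04). With other numbers the range was -0.76 to 0.81 over 164 pairs (median 0.01). Birds of the same array were left out of this check, so it cannot exclude pairing. The fit with the replicate block leaves the 4 arrays of 3X and 2X birds without weight. It gave 0 for all 4 dose counts, 636 for 3X over 2X, 1190 for 4X over 2X, 54 for 4X over 3X, 983 departures and a slope of 0.788. Not run were GC correction, region joining, other numbers of probes per region and gene lists. Signal over background was high, with at least 99.8% of spots well above it in both channels, and 6.91% to 10.3% of red spots were saturated. Without probes holding a saturated spot the dose count was 350, with 15 numbered probes, and the slope was 0.772.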

Other observations

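The tests of probe numbers and of the chromosome Z ratio below were chosen after the data were seen; the assignments of doses were planned. Many numbered probes followed the chromosome Z ratio. With labelled dose and the chromosome Z ratio in the model, limma called 143 numbered probes that rose with Z and 783 that moved against it. The W probes also moved against it, 45 of 46, and all 45 had a coefficient below -1, which only 66 of the 783 numbered probes had. Without the array of the bird labelled tetrasomic 2 the counts of 143 and 783 were 94 and 767. In 1 of 100 orders of the Z ratio over the arrays, the real one, as many probes passed, 926 against at most 2 in the others. A candidate explanation is unplaced sequence on the sex chromosomes (Z and W) among the numbered probes, a hypothesis for which the real order was the 1 of 100 with as many probes. That test does not show that the 783 come from W, since most of them had coefficients nearer to 0 than those of the called W probes.

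Numbers that follow each other may stand for sequence that lies together. Over 18073 pairs of consecutive numbers, the chromosome Z coefficients correlated at 0.442 across probes, which are not independent, against at most 0.0395 in 10000 shuffles. Of the 16 numbered probes called for the GGA16 dose, 8 had a called neighbour in number, against at most 2 in 10000 random draws. The probes 28051 to 28054, 19401 and 19402, and 11388 and 11389 make up these runs. A test with the array's design file, not used here, would show whether each run is a contig.

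The labelled doses were assigned to the arrays in 99 other ways. The main dose count of 338 was reached in 1 of the 100 assignments, the labelled one, with at most 18 in the others. With 100 assignments this makes chance unlikely for that count but does not exclude it. The 16 numbered calls were reached in 2 of 100, with a highest other count of 18, the 311 probes for 4X over 2X in 1 of 100 (highest other 11), the 1 call on other chromosomes in 1 of 100 (highest other 0) and the 2 probes against the dose in 2 of 100 (highest other 414). For 3X over 2X, 4X over 3X and departures the labelled count was 0, which any assignment reaches (100 of 100), so these say nothing about chance. For each of them 1 or 2 of the other assignments gave calls, up to 490, 3 and 929.

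With the measured GGA16 ratio of each array in place of the labelled dose and the chromosome Z ratio as a covariate, 25 numbered probes were called, 10 of them with a called neighbour, and 10 were called in all 3 fits: this one, the labelled dose alone, and the labelled dose with the Z covariate but without the array of the bird labelled tetrasomic 2.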
